A study of Mus musculus with 18 samples.

How the data were processed

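RNA levels were measured in hearts of wild-type rats and of rats homozygous for a mutation that alters titin splicing, at 1, 20 and 49 days of age, with 3 animals per genotype and age and 18 arrays in all. Per the series design text, each extract came from the ventricles of a single animal, so the arrays of a group are separate animals, while the sample titles speak of whole heart. The organism field of the labels names mouse although the descriptions, the strains and the array are rat, and the samples were treated as rat. The genotype field holds the same entry for every sample, so genotype was taken from the source and description fields. The strain background is a cross of Sprague-Dawley and Fisher rats, per the labels' protocols, and which animals are littermates is not given in the sources used here.

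Per the series design text, the authors made biotin-labelled cRNA from total RNA, hybridized it to Affymetrix rat expression arrays and processed the scanner images by robust multi-array analysis (RMA), which corrects the background of perfect-match probes and combines the probes of a probe set into a robust average. The deposited values are log2 levels per probe set, per the labels and the design text, and the submitters' processing notes name RMA without a version. They were used as deposited, with no further scaling. The table held 31099 probe sets, of which 57 control probe sets were left out of every test, so that 31042 were tested. Of these, 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 had no symbol listed. No gene was named from a probe set with several symbols. In all 14217 genes had a probe set of their own, and 4525 of them had more than 1. RMA gives every probe set a level, so a dim probe set has a level that is mostly background, and differences between dim levels are compressed. The probe sets sit mainly at the ends of transcripts and do not read most splice forms. Depth has no counterpart on arrays, and the number of animals limits the precision. Array medians lay between 5.42 and 5.50 on the log2 scale, and no pair among the 153 pairs of arrays held identical values.

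Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in a single model of the 6 groups over all 18 arrays, with 12 residual and 5.77 prior degrees of freedom. The contrasts were mutant against wild type at each age, the mean of these 3 differences, and day 20 against day 1 and day 49 against day 20 within the wild type, with the mutant's own change given beside it. Each used limma's moderated two-sided test with Benjamini-Hochberg adjustment over the tested probe sets, and a probe set was called at an adjusted p below 0.05. A change of the genotype effect with age was tested with limma's moderated F test of both interaction terms. Errors of differences are standard errors (SE) of the model, and errors of group means are standard deviations (SD).

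Gene lists were written before the data were examined, as were the tests, the alternatives and the rule for naming genes. Of 30 lists, 29 had at least 3 measured members, with 670 of 752 genes measured, 4 of them through an older or newer symbol. Each gene was represented by its probe set of highest mean level. Some genes belonged to several lists, so results of such lists are not independent. Ccn2 and Postn, for example, were in the hypertrophy and matrix lists, and Fhl1 and Csrp3 in the hypertrophy and titin-associated lists. The lists were tested against all other genes with limma's camera at its preset correlation of 0.01, with adjustment over the lists of a comparison. Camera with the correlation estimated from the residuals and fry were alternatives. Fry tests whether the genes of a list move, on balance, one way, and does not compare the list with other genes. The list of RBM20 splice targets was drawn from general knowledge, part of which comes from work on this rat line, so it is not independent of the model.

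Named genes were chosen by a fixed rule. For each genotype comparison these were the 10 largest rises and the 10 largest falls among called probe sets with 1 symbol whose 3 mutant and 3 wild-type arrays did not overlap, or, for the mean over ages, whose direction was the same at all 3 ages, with 1 probe set per gene and direction. For each age comparison they were the 8 largest rises and falls, and for the change with age the 10 smallest p-values of the F test. Always named were Rbm20, Ttn, Nppa, Nppb, Myh6, Myh7, Acta1 and Ankrd1, and for each list up to 4 called members, or values of 2 members where none was called. Where fewer qualified, all of them are named. Outside this rule, Ccnb2 at day 20, Tgfb2 and Ccne1 in the mean over ages and Rtn4 between day 20 and day 49 were chosen after their values were seen.

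Calls shared between ages were set against the number expected of independent lists, the product of both counts over the probe sets tested, per direction. The genotype effect at one age was correlated across probe sets with the wild-type change between the other ages, which shares no array with it. Probe sets are not independent replicates, so this correlation was set against the other splits of the 6 arrays of that age. All contrasts were also refitted for every other division of 3 against 3 arrays within an age (10 divisions), or for 100 drawn combinations over all ages.

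The titles number the replicates from 1 to 3 in every group. The correlation of same-numbered arrays, as deviations from their group means over all probe sets, lay between 0.105 and 0.192 for the wild type at day 20 and day 1, above 0.1 in all 3 pairs, which was the limit set for taking the numbers as a pairing. A differently numbered pair, day 20 array 1 with day 1 array 3, also passed it at 0.121. The 2 arrays numbered 2 both had high Xist and the largest gap between the 3′ and 5′ Gapdh probe sets of their groups, so sex or RNA ends could give their correlation. The pairing comes from the title numbers alone, and no source used here says that they mark a litter or a day.

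Alternatives were a restriction to brighter probe sets, only the arrays of the ages compared, an intensity trend in the prior variance, array quality weights, quantile normalization across arrays, centring of arrays on their median, the replicate number as a block, Y-linked transcripts as a covariate, stricter thresholds, 1 probe set per gene and leaving out each array in turn. Alternatives added after the data had been seen were the difference between the 3′ and 5′ Gapdh probe sets as a covariate, the 3 day 1 arrays in which it was above 1 left out or entered as a block, and the 2 mutant day 49 arrays with weak hybridization controls left out.

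The procedure was tested on simulated data for 31042 probe sets with 200 changed. In the comparison at day 49 it recovered 92% of the simulated changes of 1 on the log2 scale and 46% of those of 0.5. It made 4 false calls there, 9 at day 1 and 14 at day 20, and 0 calls when nothing was changed. In the test of the change with age it recovered 78% of changes of 1 and 14% of those of 0.5, with 7 false calls. For the mean over ages, camera called the 1 shifted list among 29, and 1 other list. The test of probe sets of a gene against each other recovered 99% of changes of 1 on the mean over ages, among 6609 pairs, with 7 false calls. Noise was drawn independently for each probe set, so the simulated data held no correlation between genes and no structure of the arrays. They cannot tell how many calls, lists or pairs such correlation or structure would add. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.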

Results

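The data describe postnatal hearts of rats with a mutation that alters the splicing of titin, the giant spring protein of the sarcomere, and of wild-type rats. Expression was read at 1, 20 and 49 days of age from 3 mutant and 3 wild-type animals per age. Age set the main structure of the arrays: the first principal component held 65.5% of the variance and ordered them by age, and the second held 8.31%. Correlations between arrays of the same group lay between 0.985 and 0.995, those between genotypes of the same age between 0.988 and 0.994, and those between ages between 0.934 and 0.988. At each age the number of animals with high Xist and low Y-linked levels was the same in both genotypes. It differed between ages, with 1 of 3 per group at day 1 and day 20 and 2 of 3 at day 49. RNA ends were less even at day 1. The 3′ Gapdh probe set exceeded the 5′ one by 0.94 ± 0.12 (SD, n = 3) on the log2 scale in the wild type and by 1.03 ± 0.37 in the mutant at that age. These gaps were 0.58 ± 0.29 and 0.49 ± 0.15 at day 20, and 0.35 ± 0.02 and 0.43 ± 0.05 at day 49.

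**Figure D1:**
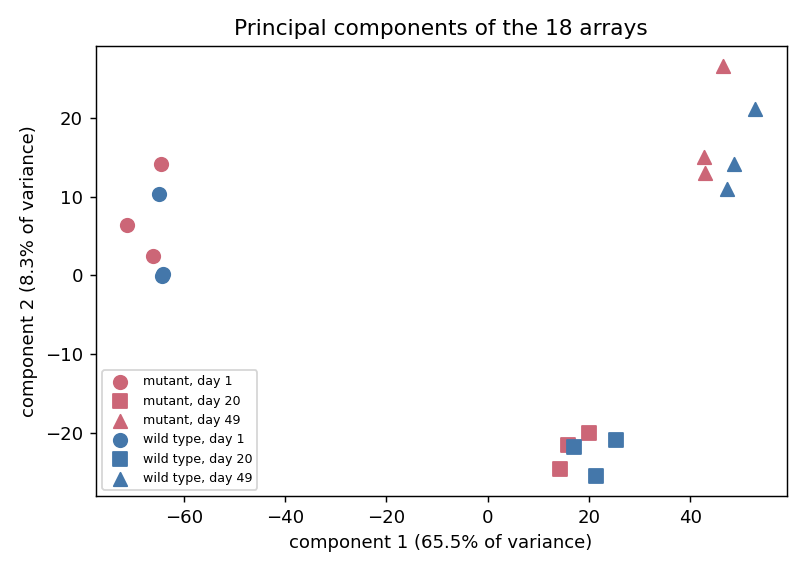
Each point is 1 array on the first and second principal components of the log2 levels, with the share of variance on the axes. Arrays separated by age, and the genotypes lay close together within an age.

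Rbm20, which encodes a muscle splicing regulator that acts on titin and which the mutation of this line is known to affect, had far lower signal in the mutant at all ages. Its first probe set stood at 5.71 ± 0.36 (SD, n = 3) in the mutant and 10.75 ± 0.13 in the wild type at day 1. It differed by -5.04 ± 0.20 (SE) at day 1, -5.11 ± 0.20 at day 20 and -4.33 ± 0.20 at day 49. In limma's moderated test the adjusted p was 8.55e-11, 6.84e-11 and 6.01e-10. The second Rbm20 probe set fell by 1.98, 1.25 and 1.09 at the 3 ages. Mutant arrays lay at 5.35 to 6.12 in the first probe set, near the array medians, and at 4.35 to 5.49 in the second. Background may hold up such levels, so the falls could be larger than these values. All 9 mutant arrays lay below all 9 wild-type arrays in the first probe set, so the genotype labels and this probe set match on each array. Where the probes lie relative to the mutation was not analysed here, so the lower signal does not by itself show less of the whole transcript. No difference was called for titin itself. Ttn was read by 1 probe set, whose place among the splice forms was not analysed here, and its differences were 0.06 ± 0.10, 0.07 ± 0.10 and 0.06 ± 0.10, with adjusted p of 0.999, 1.00 and 0.959.

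**Figure D2:**
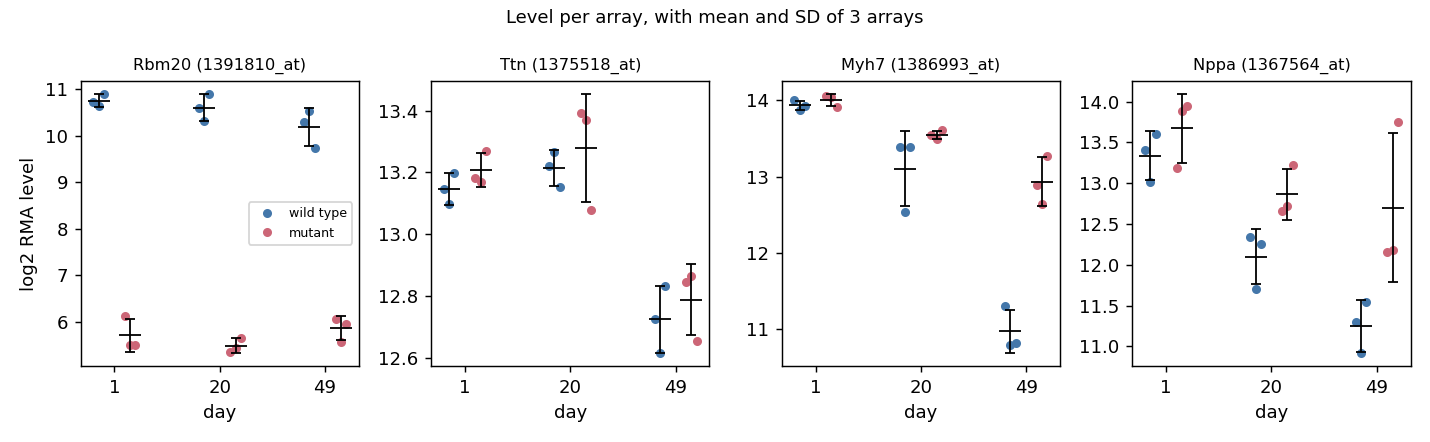
Points are log2 levels of single arrays for Rbm20, Ttn, Myh7 and Nppa by age and genotype, and black marks give the mean and SD of 3 arrays. Rbm20 separated the genotypes at every age, Ttn did not, and Myh7 was 12.93 in the mutant and 10.97 in the wild type at day 49.

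The comparison at day 1 asks which transcripts already differ in the newborn mutant heart. Saa3, an acute-phase protein, rose by 1.69 ± 0.22 (SE, n = 3 per genotype, log2 scale), Ildr2 by 1.61 ± 0.17 and Fhip2a by 1.60 ± 0.16. Opn3, an opsin, rose by 0.95 ± 0.13, Abca5, a lipid transporter, by 0.94 ± 0.14, and Pdcd4, an inhibitor of translation, by 0.89 ± 0.16. Tcap, the telethonin that caps titin at the Z-disc, rose by 0.75 ± 0.14, with Scrn1 at 1.04 ± 0.20, Plg, the plasminogen gene, at 0.66 ± 0.12 and Vsig10 at 0.64 ± 0.12. Among the falls were Dguok, a mitochondrial deoxyguanosine kinase, at -1.57 ± 0.27, and the serine protease-like Prss35 at -1.45 ± 0.27. Others were Bbip1, a subunit of the BBSome of cilia, at -1.36 ± 0.15 and the retinoid receptor Rxrg at -1.25 ± 0.22. Pgam2, the muscle phosphoglycerate mutase of glycolysis, fell by 0.87, LOC100912248 by 0.81, the calcium-binding Efhd1 by 0.79, Txlnb by 0.78 and Veph1 by 0.67. A dimmer Rxrg probe set was at 0.01, and others were at 0.23 for Ildr2 and 0.02 for Pdcd4.

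Called in all were 34 probe sets at day 1, 17 higher and 17 lower, of 21 named genes, with 2080 at an unadjusted p below 0.05. With arrays centred on their median the calls were 10 higher and 16 lower. Fitted on the day 1 arrays alone there were 4 calls. The count also rested on single arrays and was 17 without mutant array 2, 234 without mutant array 3, and 15, 111 and 17 without wild-type arrays 1, 2 and 3. The balance of directions shifted too, to 39 higher and 11 lower without mutant array 1, and to 46 higher and 18 lower without the 3 arrays whose Gapdh gap exceeded 1, which leaves 1 mutant array. Saa3, Ildr2, Fhip2a, Opn3, Bbip1 and both Rbm20 probe sets kept their call whichever array was left out. Leaving out mutant array 1, 2 or 3 ended the call of 9, 11 and 1 of the 21 named probe sets and leaving out wild-type array 1, 2 or 3 that of 12, 4 and 10.

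Fatty acid oxidation genes were lower at day 1 in 37 of 41 measured members, with a median of -0.23. Examples were Plin5 (-0.88 ± 0.24) and Hadh (-0.32 ± 0.10), although 0 passed the test over all probe sets and 0 when adjusted over the list alone. Camera gave the list an adjusted p of 3.1e-08, against 0.648 with the correlation between genes estimated from the data. Both values follow each called list below, the latter marked estimated. Atrial and conduction markers were higher in 14 of 17, among them Gja5 (0.57 ± 0.17) and Kcnj5 (0.47 ± 0.14), with 0 rises over all and 4 adjusted over the list alone (camera adjusted p = 0.0036, 0.648 estimated). Hypertrophy and wall stress markers were higher in 17 of 22, including Csrp3 (0.37 ± 0.08) and Fhl1 (0.46 ± 0.11), with 0 over all and 2 adjusted over the list alone (0.0097, 0.648 estimated). Of 33 titin-associated and Z-disc or M-band genes 1, Tcap, rose over all, and 4 rose and 1 fell adjusted over the list alone (0.032, 0.648 estimated). Without mutant array 3 the atrial (adjusted p = 0.153), hypertrophy (0.122) and titin-associated (0.0524) calls ended. The hypertrophy and titin-associated ones (0.0560 each) ended without wild-type array 1, and the titin-associated one without mutant array 2 (0.154) or wild-type array 3 (0.116). The other 25 lists had adjusted p from 0.0574 to 0.969. The median, mean and test differed in sign for 7 of them, the RBM20 splice targets, contractile filament proteins, calcium handling, ion channels, fibroblast and thymocyte markers and Y-linked transcripts.

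At day 20, around weaning, a first probe set of 2310002L09Rikl, whose function is not given in the sources used here, rose by 3.57 ± 0.15 (SE, n = 3 per genotype), a second probe set of it fell by 1.36 and another was at 1.86. Ccn2, the connective tissue growth factor, rose by 1.78 ± 0.31, Ankrd23, an ankyrin repeat protein that binds titin, by 1.67 ± 0.24, and Tnfrsf12a, the receptor of the cytokine TWEAK, by 1.16 ± 0.22. Enah, an actin regulator whose transcript is a splice target of RBM20, rose by 1.12 ± 0.12, and Kcnq1, a potassium channel of repolarization, by 0.90 ± 0.10. Other rises were Fhip2a at 2.20 ± 0.16, Msrb2, a mitochondrial methionine sulfoxide reductase, at 1.35 ± 0.13, Pdcd4 at 0.91 ± 0.16 and Bex1 at 0.91 ± 0.16. Ephx2, the soluble epoxide hydrolase, fell by 3.31 with an SE of 0.55, Bbip1 by 1.35, Klhdc7a by 0.90, the chloride and proton exchanger Clcn4 by 0.78, H2al2l by 0.62 and Mlip, a lamin-interacting protein of muscle, by 0.61. Ephx2 levels also ranged widely within groups at day 1, from 5.29 to 7.78 in the mutant and from 5.59 to 7.91 in the wild type, and the genotypes overlapped at day 49. Dimmer Enah probe sets were at 0.05 and 0.42, and another one of Clcn4 at -0.12 and of Pdcd4 at 0.12.

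Of the 31042 probe sets tested at day 20, 1326 had an unadjusted p below 0.05, a smaller share than the 0.05 expected if nothing differed. In total 43 were called, 24 higher and 19 lower, of 26 named genes. By gene 19 were higher and 8 lower, 1 of them in both directions, and with 1 probe set tested per gene 28 were higher and 8 lower. There were 22 calls without mutant array 2, and 24, 21 and 21 without wild-type arrays 1, 2 and 3. 2310002L09Rikl, Fhip2a, Ankrd23, Msrb2, Enah, Kcnq1, Bbip1 and Rbm20 kept their calls whichever array was left out. Of 19 named probe sets, 5, 9 and 7 lost theirs without mutant array 1, 2 or 3, and 7, 9 and 8 without wild-type array 1, 2 or 3.

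Cell cycle genes were higher in 42 of 45 at day 20, with values of 0.94 ± 0.19 for Mki67, the proliferation antigen, 1.01 ± 0.22 for the cyclin Ccnb2 and 0.80 ± 0.17 for the mitotic kinesin Kif20a. Of the 45, 0 passed over all probe sets and 13 rose when adjusted over the list alone, and camera's adjusted p was 8.1e-24 (0.0242 estimated). Hypertrophy and wall stress markers rose in 3 of 22, Ccn2, Tnfrsf12a and Fhl1 (0.74 ± 0.11), and in 6 adjusted over the list alone, with 18 of 22 higher (camera adjusted p = 3.5e-12, 0.0172 estimated). Titin-associated genes rose in 2 of 33, Ankrd23 and Fhl1, and adjusted over the list alone 4 rose and 1 fell (9.7e-07, 0.0456 estimated). Weaker calls concerned 3 other lists. Extracellular matrix genes were higher in 34 of 43, with Ccn2 the 1 rise by either adjustment (adjusted p = 0.0016, 0.786 estimated). Fatty acid oxidation genes were lower in 31 of 41 with 0 falls by either adjustment (adjusted p = 0.0089, 0.786 estimated). Immediate early genes, with Atf3 at 1.21 ± 0.32, had 0 rises over all and 1 adjusted over the list alone (adjusted p = 0.0231, 0.565 estimated). Each of these weaker calls ended when single arrays were left out. The matrix call ended without mutant array 1 (0.0647) or 3 (0.196) or wild-type array 3 (0.0835), and fatty acid oxidation without the same arrays (0.192, 0.0636 and 0.222). That of the immediate early genes ended without mutant array 1 (0.126) or wild-type array 2 (0.0755). The number of called lists was 11 without mutant array 2. The 23 other lists had adjusted p from 0.0513 to 0.922, and signs of median, mean and test differed for 3, the muscle splicing regulators and the atrial and skeletal muscle markers.

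The comparison at day 49, in young adult hearts, gave the most calls of the 3 ages. Myh7, the slow beta-myosin heavy chain, rose by 1.96 ± 0.19 (SE, n = 3 per genotype), from 10.97 ± 0.29 (SD) in the wild type to 12.93 ± 0.32. Its dimmer probe set was at 2.81 ± 0.69 with an adjusted p of 0.0818. Casq1, the skeletal calsequestrin, rose by 1.45 ± 0.15 and Mybpc2, the fast skeletal myosin-binding protein C, by 1.41 ± 0.12, while skeletal muscle markers were not called as a list (camera adjusted p = 0.793). Penk, the enkephalin precursor, rose by 1.95 ± 0.36, Ankrd23 by 1.90 ± 0.24, Bex1 by 2.29 ± 0.16, and the G-protein subunit Gnao1 by 1.44 ± 0.20. The lectin Reg3g rose by 1.40 ± 0.30, Fhip2a by 1.93 ± 0.16 and the first 2310002L09Rikl probe set by 3.67 ± 0.15. Lower were Ano5, an anoctamin of muscle, at -2.74 ± 0.31, and Scn4b, the beta-4 subunit of the sodium channel, at -2.45 ± 0.31. Sctr, the secretin receptor, was at -1.99 ± 0.15 and Gabrb2, a subunit of the GABA-A receptor, at -1.78 ± 0.28. Fubp3 fell by 2.58, Hs3st5, a heparan sulfate sulfotransferase, by 1.58, the second 2310002L09Rikl probe set by 1.57, Trdn, the triadin of the calcium release complex, by 1.47 and Bbip1 by 1.37. Other probe sets of these genes differed less: a brighter one of Fubp3 was at 0.24, those of Trdn at -0.28, -0.57 and 0.11, and dimmer ones of Gabrb2, Hs3st5 and Mybpc2 at -0.09, -0.32 and 0.27.

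At this age 188 probe sets were called, 73 higher and 115 lower, of 124 named genes, with 2534 at an unadjusted p below 0.05. The count was 109, 120 and 123 without wild-type arrays 1, 2 and 3. The excess of falls also depended on single arrays, with 79 higher and 77 lower without mutant array 3 and 57 and 63 without wild-type array 2. It was largest without wild-type array 1, with 38 and 71, and without mutant array 2, with 53 and 90. Hybridization controls, which read the array chemistry, were lower on the mutant arrays (9.11 ± 0.75, SD) than on the wild-type ones (9.99 ± 0.16), with mutant arrays 1 and 2 lowest. Without those 2 arrays, which leaves 1 mutant array whose spread is assumed from the other groups, 116 probe sets were called. Of 21 named probe sets 17 kept their call whichever array was left out. Fubp3 lost its call without any 1 of the 6 arrays, Reg3g without each but mutant array 1, and Trdn without each but mutant array 2. Penk lost its call without mutant arrays 1 or 2 or wild-type arrays 1 or 3. The adjusted p of these was up to 0.174.

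**Figure D3:**
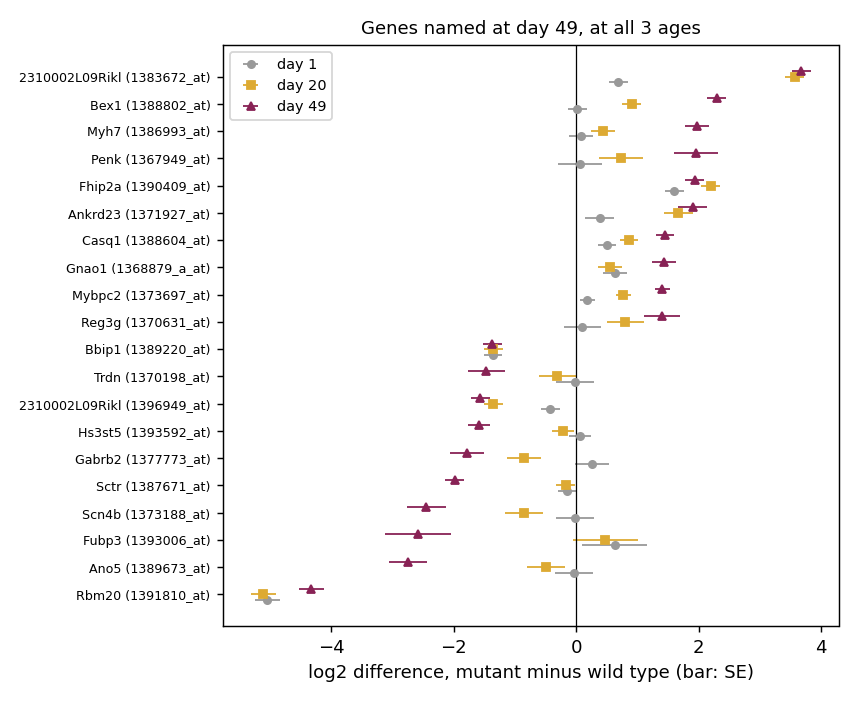
Log2 differences between mutant and wild type at the 3 ages for the genes named at day 49, each from 3 arrays per genotype, with bars for the SE. Rbm20, Bbip1 and Fhip2a lay at similar values at all ages, and Myh7 was at 0.07 at day 1 and 1.96 at day 49.

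Hypertrophy and wall stress markers were higher in 20 of 22 at day 49, with rises of Myh7 and Postn, the matrix protein periostin (1.12 ± 0.23), over all probe sets and 8 rises adjusted over the list alone. Camera's adjusted p was 3.2e-10 (0.0347 estimated). The atrial natriuretic peptide gene Nppa stood at 1.45 ± 0.33 with an adjusted p of 0.0597 in limma's moderated test. Without mutant array 3 its difference was 0.92, with an adjusted p of 0.167. Its levels in the mutant ranged widely, 12.70 ± 0.91 (SD) against 11.25 ± 0.31 in the wild type. Values for Nppb (0.21 ± 0.24), Myh6 (-0.16 ± 0.12), Acta1 (0.19 ± 0.12) and Ankrd1 (0.24 ± 0.14) did not pass. Without mutant array 3 those of Nppb, Acta1 and Ankrd1 were 0.02, 0.02 and 0.13. Extracellular matrix genes were higher in 40 of 43, with 1 rise, Postn, over all and 4 adjusted over the list alone (camera adjusted p = 9.1e-13, 0.287 estimated). Ion channels and connexins had 3 falls, Scn4b, Kcnd2 (-0.88 ± 0.17) and Kcnj11 (-0.59 ± 0.13), and 1 rise, Kcnq1 (0.96 ± 0.10), among 24, with 7 falls and 1 rise adjusted over the list alone (0.0051, 0.114 estimated).

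Transcript lists of energy metabolism were called lower at day 49 by camera at its preset correlation, though not with an estimated one. Of 41 fatty acid oxidation genes 37 were lower and 2 fell, Bdh1 of ketone metabolism at -0.62 ± 0.13 and Hadh at -0.49 ± 0.10, with 7 falls adjusted over the list alone (camera adjusted p = 1.1e-07, 0.487 estimated). Of 47 TCA cycle and respiratory chain genes 41 were lower and 1 fell both over all and adjusted over the list alone, the muscle cytochrome oxidase subunit Cox7a1 at -1.02 ± 0.18 (3.1e-06, 0.439 estimated). Cell cycle genes were higher in 38 of 45, with Cks2 at 0.85 ± 0.22 and Cdk1 at 0.71 ± 0.20, 0 rises over all and 1 adjusted over the list alone (1.6e-07, 0.371 estimated). Markers of other cells were called as well, with 0 members passing by either adjustment. These were fibroblasts, with Col1a1 at 0.56 ± 0.17 (adjusted p = 0.0026, 0.487 estimated), leukocytes, with Coro1a at 0.48 ± 0.17 (adjusted p = 0.0051, 0.487 estimated) and erythroid cells, with Alas2 at 1.17 ± 0.47 (adjusted p = 0.0445, 0.612 estimated). The fibroblast and leukocyte calls ended without mutant array 3 (0.355 each), and the erythroid call ended without mutant array 1 (0.383) or 3 (0.0652) or wild-type array 2 (0.162) or 3 (0.178). The 20 remaining lists had adjusted p from 0.130 to 0.961. Median, mean and test differed in sign for 7, the RBM20 splice targets, muscle splicing regulators, circadian clock and Y-linked transcripts and the atrial, skeletal muscle and adipocyte markers.

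**Figure D4:**
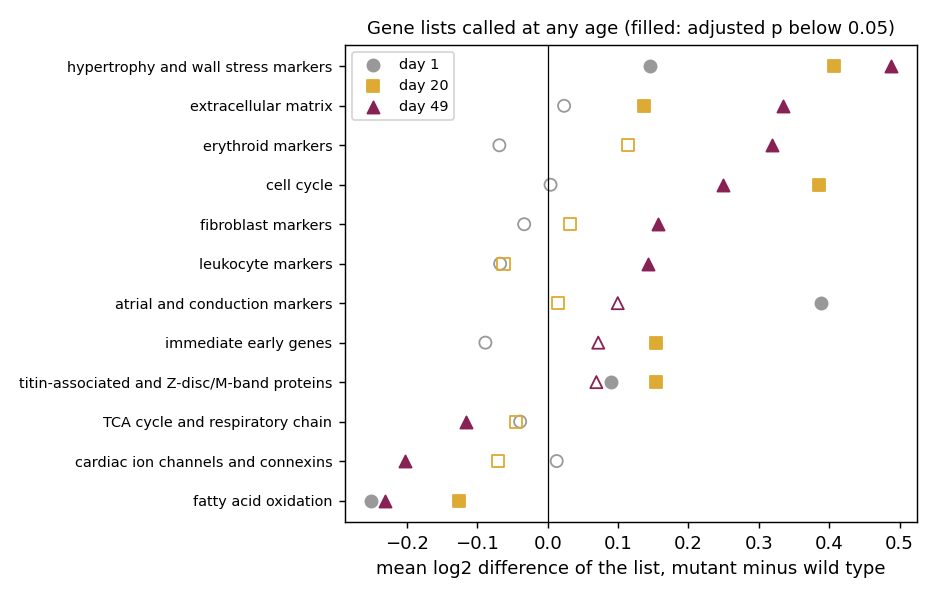
Mean log2 difference between mutant and wild type over the members of each gene list called at any age, with filled symbols for camera's adjusted p below 0.05. The mean of the hypertrophy and wall stress markers was above 0 at all ages and that of fatty acid oxidation below 0. Camera with an estimated correlation called 0 lists at day 1, 3 at day 20 and 1 at day 49.

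Averaged over the 3 ages, the comparison tests the mean genotype effect from 9 animals per genotype, whether or not the effect changed with age. Csrp2, a LIM protein, rose by 1.32 ± 0.32 (SE), Ankrd23 by 1.32 ± 0.14, and Enah by 0.99 ± 0.07. Myot, myotilin of the Z-disc, rose by 0.66 ± 0.10, Fhl1 by 0.53 ± 0.06 and Csrp3 by 0.38 ± 0.05. Fhip2a rose by 1.91 ± 0.09, 2310002L09Rikl in its first probe set by 2.64 ± 0.09, Bex1 by 1.07 ± 0.09, and the carboxypeptidase Cpa6 by 0.98 ± 0.17. Ildr2 rose by 0.98 ± 0.14, Casq1 by 0.94 ± 0.09 and Penk by 0.91 ± 0.21. Rbm20 fell by 4.83, Bbip1 by 1.36, 2310002L09Rikl in its second probe set by 1.12, Scn4b by 1.11, Ano5 by 1.09, the chemokine Cxcl11 by 0.96, Rxrg by 0.80, Sctr by 0.77, Prune2 by 0.72 and the potassium channel Kcnk2 by 0.69. Other probe sets differed less or the opposite way for Prune2 (0.05 and 0.29), Kcnk2 (-0.07), Rxrg (-0.03), Enah (-0.03 and 0.39) and Ildr2 (0.17, 0.95 and 0.58). Bex1, Sctr, Ano5 and 2310002L09Rikl also passed the test of a change with age.

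The average called 433 probe sets, 204 higher and 229 lower, of 297 named genes, with 2988 at an unadjusted p below 0.05. It fell to 281 without wild-type day 1 array 1 and to 284 without wild-type day 20 array 2. Of 23 named probe sets 20 kept their call whichever array was left out, and Csrp2, Penk and Nppa lost theirs in some of these fits, with adjusted p up to 0.0990. Without wild-type day 20 array 2, wild-type day 49 array 1 or mutant day 20 array 3 all 3 were lost.

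Hypertrophy and wall stress markers rose in 7 of 22 on average, Ccn2 (0.90 ± 0.18), Tnfrsf12a (0.88 ± 0.13), Nppa (0.85 ± 0.19), Myh7 (0.83 ± 0.11), Fhl1, Csrp3 and Tgfb2. Adjusted over the list alone 12 rose and 0 fell. This call held with an estimated correlation (camera adjusted p = 1.4e-13, 0.00998 estimated). Cell cycle genes had 6 rises, among them Cdkn3 (0.79 ± 0.17) and Cks2 (0.71 ± 0.13), and 1 fall, the cyclin Ccne1 (-0.32 ± 0.07), among 45. Adjusted over the list alone there were 17 rises and 1 fall (1.6e-12, 0.202 estimated). Fatty acid oxidation genes fell in 4 of 41, Plin5 (-0.65 ± 0.14), Hadh (-0.38 ± 0.06), Eci2 (-0.26 ± 0.06) and Pdk2 (-0.25 ± 0.05), and in 13 adjusted over the list alone (1.3e-11, 0.297 estimated). Titin-associated genes rose in 4 of 33, Ankrd23, Myot, Fhl1 and Csrp3, and in 8 adjusted over the list alone (0.00096, 0.235 estimated).

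Extracellular matrix genes were higher in 40 of 43, Ccn2 being the 1 rise by either adjustment (2.4e-08, 0.343 estimated). TCA cycle and respiratory chain genes were lower in 42 of 47 with 1 fall, Cox7a1 (-0.42 ± 0.10), and 2 adjusted over the list alone (2.9e-05, 0.346 estimated). Glycolysis genes had 1 fall, Pgam2 (-0.67 ± 0.08), and 3 adjusted over the list alone (0.0171, 0.343 estimated), a call that ended without mutant day 1 array 3 (0.0521) or wild-type day 1 array 2 (0.0508). Antigen presentation and interferon response genes were lower in 21 of 27, with Cd74 at -0.30 ± 0.09 and 0 falls by either adjustment (0.0189, 0.584 estimated). They lost the call without mutant day 20 arrays 2 (0.0788) or 3 (0.0771), mutant day 49 arrays 1 (0.0931) or 2 (0.113) or wild-type day 20 array 1 (0.0550). Ion channels had 2 falls, Scn4b and Abcc8 (-0.36 ± 0.07), and 1 rise, Kcnq1 (0.63 ± 0.06), with 8 falls and 1 rise adjusted over the list alone (0.0369, 0.235 estimated). This call ended without mutant day 1 array 2 (0.0798), mutant day 20 array 3 (0.112) or mutant day 49 arrays 1 (0.0716) or 3 (0.0660). It also ended without wild-type day 1 array 3 (0.0551), wild-type day 20 array 3 (0.0584) or wild-type day 49 array 1 (0.0845).

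RBM20 splice targets were not called as a list on average (adjusted p = 0.459), though Enah, Myh7 and Lrrfip1 (0.34 ± 0.07) rose and Mlip (-0.52 ± 0.06) fell among 30. Adjusted over the list alone 3 rose and 2 fell. A second Lrrfip1 probe set was at -0.28. Muscle splicing regulators had 1 fall, Rbm20 itself, among 33 (0.589), and calcium handling genes had 1 rise, Casq1, and 1 fall, Hrc (-0.34 ± 0.07), among 30 (0.969). Contractile filament proteins had 1 rise, Myh7, among 19 (0.180) and skeletal muscle markers had 1 rise, Mybpc2 (0.79 ± 0.07), among 21 (0.780). Adjusted over the list alone these counts were 0 rises and 1 fall, 1 rise and 3 falls, 5 rises and 1 fall, and 1 rise. Median, mean and test differed in sign for the RBM20 splice targets, calcium handling and skeletal muscle markers. Markers of other cell types were not called on average. Adjusted p was 0.961 for endothelial, 0.141 for fibroblast, 0.491 for smooth muscle and pericyte, 0.242 for erythroid and 0.391 for atrial and conduction markers. It was 0.839 for adipocyte, 0.911 for leukocyte, 0.50 for thymocyte and 0.810 for Schwann and neuronal markers. Within them Nppa rose, and Dkk3 (-0.30 ± 0.07) and Smtn (-0.27 ± 0.05) fell, and Satb1 (0.26 ± 0.06) rose. Heat shock and unfolded protein response (0.839), atrophy, autophagy and proteasome (0.550), immediate early (0.391), circadian clock (0.584), Y-linked (0.95) and developmentally regulated growth factor and imprinted (0.845) lists were not called and had 0 members past the threshold over all probe sets. Adjusted over the list alone, 1 heat shock gene rose and 1 clock gene and 1 growth factor or imprinted gene fell.

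Some probe sets were called at every age. Calls shared in the same direction numbered 10 between day 1 and day 20 (0.024 expected of independent lists), 9 between day 1 and day 49 (0.10 expected) and 28 between day 20 and day 49 (0.13 expected). The counts in opposite directions were 0, and the animals differed at each age. At all 3 ages 8 probe sets were called, both of Rbm20, those of Bbip1 and Fhip2a and 4 with no symbol listed. The expected numbers treat probe sets as independent, although both Rbm20 probe sets were among the shared calls. The ages also shared an estimate of the spread. Bbip1, and Pdcd4 called at day 1 and day 20, lie close to Rbm20 in the mouse gene order. The first shared count was 6 without mutant day 1 array 2 and 5 without wild-type day 1 array 3. The second was 16 without mutant day 1 array 3, 5, 17 and 5 without wild-type day 1 arrays 1, 2 and 3. The third was 17 without mutant day 20 array 2 and 18 without either wild-type day 20 array 2 or 3.

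Whether the genotype effect changed with age was tested directly, and 23 probe sets of 14 named genes passed limma's moderated F test. Its unadjusted p was below 0.05 for 1354 of 31042 probe sets, a smaller share than the 0.05 expected if nothing differed. Bex1 differed by 0.02 ± 0.16 at day 1, 0.91 ± 0.16 at day 20 and 2.29 ± 0.16 at day 49. Myh7 differed by 0.07 ± 0.19, 0.44 ± 0.19 (0.15 without wild-type day 20 array 2) and 1.96 ± 0.19, and Mybpc2 by 0.18 ± 0.12, 0.77 ± 0.12 and 1.41 ± 0.12 (n = 3 per genotype and age). Kcnq1 (0.04, 0.90 and 0.96), Msrb2 (0.16, 1.35 and 1.14) and 2310002L09Rikl (0.68, 3.57 and 3.67 in its first probe set) had higher values from day 20 on. Sctr (-0.15, -0.17 and -1.99) and Hs3st5 (0.07, -0.21 and -1.58) were lower at day 49. Dguok (-1.57, 0.98 and 0.35) was lower at day 1, and Ccl5, a chemokine, went from -0.76 at day 20 to 0.84 at day 49. The day 49 value of Dguok lay between 0.15 and 0.69 when single arrays were left out. At day 20 Sctr was at 0.02 without mutant array 1 and Hs3st5 at -0.07 without wild-type array 3. The count was 35 without mutant day 1 array 1, 58 without mutant day 1 array 3, 38 without wild-type day 1 array 2 and 14 without wild-type day 49 array 3. Myh7 and Mybpc2 lost the call without wild-type day 49 arrays 2 or 3, Hs3st5 without mutant day 49 array 2 or wild-type day 49 array 2, and Msrb2 without wild-type day 1 array 1. Dguok lost it without mutant day 1 array 2 or wild-type day 1 arrays 1 or 3. Ccl5 lost it without any 1 of 6 arrays, namely mutant day 20 arrays 2 and 3, mutant day 49 arrays 1 and 2 and wild-type arrays 3 of day 20 and day 49. The adjusted p of these was up to 0.0743.

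Postnatal maturation of the wild-type heart gives the background of these differences. From day 1 to day 20, Rpl3l, a ribosomal protein of muscle, rose by 6.08 ± 0.17 (SE, n = 3 per age), Akr1c15 by 5.41 ± 0.14 and the mitochondrial acetyl-CoA synthetase Acss1 by 5.33 ± 0.26. The splicing regulator Rbfox1 rose by 4.74 ± 0.11, Tuba8 by 4.41 ± 0.23, LOC100909396 by 4.24 ± 0.24, the mitochondrial creatine kinase Ckmt2 by 4.08 ± 0.18 and Asph by 4.0 ± 0.11. Genes of dividing cells fell, with Ect2 at -4.75, Mki67 at -4.34, Pclaf at -4.33, Ccnb2 at -4.29 and Cks2 at -4.24. So did Slc16a12 at -4.64, Kif26b at -4.51 and Cdhr1 at -4.44. Other probe sets were as low as -0.02 for Rbfox1 and -0.42 for Asph, and one of Kif26b was at -0.05. The natriuretic peptide genes Nppa and Nppb fell by 1.24 and 0.92 and Myh7 by 0.83, with its dimmer probe set at 0.56, while Myh6, the fast alpha-myosin, rose by 0.35 ± 0.12 and in its dimmer probe set by 3.10 ± 0.68. Without wild-type day 20 array 2 the differences of Myh7 and Nppb were -0.54 and -0.60, and without wild-type day 1 array 2 that of Myh6 was 0.23. The dimmer Myh6 and Myh7 probe sets were low on wild-type day 20 array 2 as well, with a Gapdh gap of 0.90, at 9.82 and 6.6, against 11.87 and 11.81 and 9.80 and 9.68 on the others. Since that gap also fell with age, their changes are not separable from RNA ends. In all 8737 probe sets were called, 3907 higher and 4830 lower, with 8764 in the mutant. The balance was 4096 and 4538 with quantile normalization and 3548 and 4979 with centred arrays. The genotypes shared 6608 in direction (1249 expected of independent lists) against 4 opposite. The 0.35 rise of Myh6 and the fall of the second Rbm20 probe set (-0.46 ± 0.15) lost their calls without single arrays. This was so for Myh6 without wild-type day 1 array 2 or any wild-type day 20 array. For Rbm20 it was so without any wild-type day 1 array or day 20 arrays 2 or 3, with adjusted p up to 0.186.

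Of 45 cell cycle genes 40 fell from day 1 to day 20 over all probe sets and 41 adjusted over the list alone (camera adjusted p = 8.8e-35, 0.0110 estimated). Of 19 developmentally regulated growth factors and imprinted genes 14 fell, Mest by 3.74, Tnc by 3.06, H19 by 2.93 and Plagl1 by 2.87, and 2 rose, with the same counts adjusted over the list alone (1.1e-06, 0.0477 estimated). Rises prevailed among TCA cycle and respiratory chain genes (36 of 47 rose, 41 adjusted over the list alone, adjusted p = 4.3e-14, 0.0948 estimated). So they did among fatty acid oxidation genes (26 rose and 4 fell of 41, 34 and 4 adjusted over the list alone, adjusted p = 7.2e-11, 0.176 estimated) and antigen presentation genes (16 of 27 rose by either adjustment, adjusted p = 1.2e-07, 0.133 estimated). Examples were Cox7a1 (1.32 ± 0.18), Ucp3 (2.10 ± 0.30) and Cd74 (3.12 ± 0.15). Hypertrophy and wall stress markers fell in 12 of 22 and in 13 adjusted over the list alone, among them Tnfrsf12a by 2.49 and Ccn2 by 1.67 (0.0011, 0.176 estimated).

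A further 7 lists were called between day 1 and day 20, and none of them with an estimated correlation. These were leukocyte markers (8 of 36 rose, adjusted p = 0.0021, 0.216 estimated), fibroblast markers (12 rose and 5 fell of 19, adjusted p = 0.0021, 0.342 estimated) and atrophy, autophagy and proteasome (10 rose and 1 fell of 29, adjusted p = 0.0037, 0.216 estimated). Adipocyte markers (4 of 15 rose, adjusted p = 0.0039, 0.176 estimated), the circadian clock (9 rose and 2 fell of 18, adjusted p = 0.0089, 0.176 estimated) and heat shock genes (11 rose and 5 fell of 25, adjusted p = 0.0144, 0.216 estimated) were called too. In the order given, and adjusted over the list alone, the rises were 8, 12, 11, 4, 9 and 14 and the falls 0, 5, 1, 0, 3 and 5. Muscle splicing regulators had 15 falls and 4 rises among 33, with 17 falls and 5 rises adjusted over the list alone (0.0382, 0.176 estimated). This call ended without wild-type day 1 array 2 (0.0634) or 3 (0.0559) or wild-type day 20 array 2 (0.0737). Rbfox1 rose against the direction of that list, and Hnrnpa1 fell by 1.11. The 16 other lists had adjusted p from 0.0572 to 0.990, and signs of median, mean and test differed for 3, glycolysis, immediate early genes and smooth muscle and pericyte markers.

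From day 20 to day 49 in the wild-type heart, Tnni1, the slow skeletal troponin I, fell by 3.72, Myl4, the atrial and embryonic myosin light chain, by 3.23, Myh7 by 2.14 and Ttn by 0.49. Alox15, a lipoxygenase, fell by 4.29, Postn by 2.95, the fibrillin Fbn2 by 2.38, the imprinted H19 by 2.23 and LOC102554253 by 2.03. Rises were Ces1d, a carboxylesterase, at 3.15 ± 0.21 (SE, n = 3 per age), Bdh1 at 3.12 ± 0.19, Slfn4 at 2.95 ± 0.31, and Sctr at 2.66 ± 0.15. Scn4b was at 2.62 ± 0.31, Ano5 at 2.48 ± 0.31, Penk at 2.38 ± 0.36 and RT1-Bb, of MHC class II, at 2.36 ± 0.40. Other probe sets of Slfn4 and RT1-Bb were at 0.29 and 0.03.

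Calls numbered 2974, 1097 higher and 1877 lower, with 3151 in the mutant. The balance depended on scaling, with 1380 and 1623 under quantile normalization and 912 and 2022 with centred arrays. The genotypes shared 1794 in direction (160 expected) against 3 opposite. There were 1794 without wild-type day 20 array 1, 1727 without wild-type day 20 array 2 and 1602 without wild-type day 49 array 1. Day 49 arrays carried Bacillus spike-in signal that the other arrays lacked, with the dap control probe sets at 6.33 ± 0.33 (SD, n = 6) against 3.24 ± 0.04 (n = 12), so age and array processing moved together in this comparison. The sex balance moved as well, with high Xist in 1 of 3 wild-type animals at day 20 and 2 of 3 at day 49. With Y-linked transcripts as a covariate 2587 probe sets were called. Antigen presentation and interferon response genes rose in 22 of 27, and 23 adjusted over the list alone, among them Irf7 (1.85 ± 0.26), Psmb8 (1.51 ± 0.18) and Psmb9 (1.46 ± 0.20), with a camera adjusted p of 1.7e-21 (0.0130 estimated). Leukocyte markers rose in 16 of 36 and fell in 1, S100a9, with 19 and 2 adjusted over the list alone (3.6e-09, 0.0596 estimated).

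Extracellular matrix genes fell in 13 of 43 and rose in 1, Col8a1 (1.51 ± 0.26), with 16 falls and 1 rise adjusted over the list alone (6.9e-07, 0.341 estimated). Muscle splicing regulators fell in 10 of 33, and 11 adjusted over the list alone, Hnrnpa1 by 0.62 and U2af1 by 0.53 (0.00030, 0.0527 estimated). Growth factor and imprinted genes fell in 7 of 19, and 8 adjusted over the list alone, Igf2 by 1.76 (0.0034, 0.157 estimated). RBM20 splice targets fell in 7 of 30 and rose in 1, Rtn4, with 10 and 1 adjusted over the list alone (0.0191, 0.129 estimated). Contractile filament proteins fell in 4 of 19 and rose in 1 by either adjustment (0.0442, 0.157 estimated). Without wild-type day 49 array 2 both of these last calls ended (0.0690 each), and the contractile one also without wild-type day 20 array 3 (0.0751). The 22 other lists had adjusted p from 0.0728 to 0.919, and signs of median, mean and test differed for the endothelial, smooth muscle and pericyte and adipocyte markers.

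The genotype effect was also set against wild-type maturation between the other ages. Across 31042 probe sets, which are not independent replicates, Pearson's r was 0.02 at day 1, -0.19 at day 20 and -0.20 at day 49. Among the calls, 17 of 34 at day 1, 31 of 43 at day 20 and 143 of 188 at day 49 (76.1%, against 53.5% of all probe sets) had a sign opposite to the wild-type change. Sctr, Scn4b and Myh7 at day 49 were among them. At day 1 the sign of r turned with the arrays used, to -0.05 without mutant array 1 and -0.01 without wild-type array 1, and it was 0.07 and 0.05 without array 2 of the mutant and the wild type. At day 20 r was -0.10 without wild-type array 3.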

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

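The tests on the 3 day 1 arrays with uneven RNA ends, the Gapdh end difference as a covariate, the spike-in signal, the removal of the weakly hybridized arrays and the splits for wild-type maturation, with all arrays and with single arrays left out, were chosen only after the results were seen.

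The genotype effect differed between ages by limma's F test for 14 named genes, of which the 10 with the smallest p follow, with effects of mutant minus wild type at day 1, day 20 and day 49 from 3 arrays per genotype. The adjusted p was 1.35e-06 for 2310002L09Rikl (0.68, 3.57 and 3.67), 0.000412 for Bex1 (0.02, 0.91 and 2.29), 0.000806 for Sctr (-0.15, -0.17 and -1.99) and 0.0124 for Kcnq1 (0.04, 0.90 and 0.96). It was 0.0140 for Myh7 (0.07, 0.44 and 1.96, the second 0.15 without wild-type day 20 array 2), 0.0148 for Mybpc2 (0.18, 0.77 and 1.41) and 0.0171 for Msrb2 (0.16, 1.35 and 1.14). For Dguok (-1.57, 0.98 and 0.35), Hs3st5 (0.07, -0.21 and -1.58) and Ccl5, which went from -0.76 to 0.84 between day 20 and day 49, it was 0.0182. The smaller of these effects moved with single arrays, that of Dguok at day 49 between 0.15 and 0.69. Of 100 splits of the arrays within ages, 14 gave as many probe sets past the threshold, so chance could not be excluded for the count of 23. The highest of the other splits gave 454, which points to a structure of the samples.

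At day 1, 2 of the 10 splits of the 6 arrays gave at least the 34 calls of the genotypes, the other one 1697, several times the real count, which points to a structure of the samples, and 10 splits are too few for a share under 0.05. That split set mutant arrays 1 and 2 and wild-type array 2 against the rest, and these 3 arrays had a Gapdh end difference above 1. With this class of arrays as a block, 39 probe sets were called, 30 of them among the 34, and the median ratio of the effect to its value without the block was 0.995, which argues against uneven RNA ends as the whole cause of the 34 calls. Of the 34, 10 were shared in direction with day 20 (0.024 expected of independent lists) and 9 with day 49 (0.10 expected), both Rbm20 probe sets among them. These counts, with 0 opposite and in other animals, argue against a structure of the day 1 arrays as the source of these shared calls. For the others it stays open beside genotype, and leaving the 3 arrays out decides nothing, since it leaves 1 mutant array with which the 34 were selected.

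Control probe sets outside the comparisons carried signal on the arrays of a single age. The Bacillus dap probe sets, which read RNA added before labelling, were at 6.33 ± 0.33 (SD) on the 6 day 49 arrays against 3.24 ± 0.04 on the other 12, and 21 of 24 spike-in probe sets had no overlap between these sets of arrays. All 6 day 49 arrays lay above every other array and the genotypes overlapped, which argues against a batch marked by the spike-in as the source of the 188 calls at day 49. Leaving out both mutant arrays with weak hybridization controls leaves 1 mutant array, with which the 188 had been selected, so the median ratio of 1.04 to the effect of all arrays does not decide, and weak controls and genotype cannot be told apart there. Between day 49 and day 20 of the wild type the smallest gap in the dap level was 2.64, so age and a batch cannot be told apart for the 2974 calls of that comparison, because no array of another age carried the signal. The share of animals with high Xist also differed between these ages.

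The genotype effect ran against wild-type maturation at day 20 (r -0.19) and day 49 (-0.20) but not at day 1 (0.02). The mean over the 3 ages was -0.13. Of 100 drawn splits within ages 4 gave an absolute value as large, the real one included, at 0.127 against 0.129 in the highest other. This share lies so close to 0.05 that a draw of the possible splits does not exclude chance. The share was 0.05 or more without mutant day 1 arrays 2 or 3 (6 splits each), mutant day 20 arrays 1 (5) or 3 (6), mutant day 49 array 2 (6), wild-type day 1 array 2 (9), wild-type day 49 array 1 (5) or wild-type day 20 array 3, where the mean was -0.09 and 13 splits were as large. At single ages 10 splits are too few for a share under 0.05: as large a value came in 8 at day 1 (0.0172, highest other 0.139), 2 at day 20 (0.192 and 0.281) and 1 at day 49 (0.204 and 0.142). With the Gapdh end difference as a covariate r at day 49 was -0.195. This does not decide on uneven RNA ends, since only the genotype effect was adjusted and not the wild-type change, along which the gap also fell. At day 49 the gap was 0.40 to 0.48 on mutant and 0.33 to 0.36 on wild-type arrays, without overlap. A delayed maturation of the mutant heart may be a candidate explanation beside uneven RNA ends, the ages at sampling and the cell composition, and the latter 2 were not tested.

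The remaining splits were counted in the same way. For the mean over ages 1 of 100 splits, the real one, gave as many as 433 calls and the highest other 172, so chance could be excluded. Its 9 called lists were matched by 11 of 100 splits, with 12 in the highest other, and chance could not be excluded. For single comparisons the 10 splits are too few for a share under 0.05. The calls at day 20 were 43 against 4 in the highest other, those at day 49 188 against 0, those between day 20 and day 1 of the wild type 8737 against 1, and those between day 49 and day 20 2974 against 0, each matched by the real split alone (1 of 10). Called lists numbered 4 against 5 in the highest other at day 1, 6 against 9 at day 20 and 9 against 11 at day 49, with as many in 5, 4 and 3 of 10 splits. In the wild type they numbered 13 against 11 between day 1 and day 20 and 7 against 11 between day 20 and day 49, with as many in 1 and 5 of 10 splits.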

How the results depend on the processing

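The 3 day 1 arrays left out or entered as a block for their RNA ends, the Gapdh end difference as a covariate and the weakly hybridized arrays left out were tests chosen only after the results were seen. Each alternative changed 1 choice.

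With array quality weights the calls numbered 135 at day 1, 98 at day 20, 678 for the mean over ages, 4787 between day 49 and day 20 of the wild type and 43 for the change with age, against 34, 43, 433, 2974 and 23, and the cause was not tested. Fitted on the arrays of day 1 only, there were 4 calls at that age, with fewer arrays to estimate the spread. Without the 3 day 1 arrays with uneven RNA ends there were 64 at day 1 and 41 for the change with age, with 1 mutant and 2 wild-type arrays left at day 1, and the cause was not tested. Without both weakly hybridized arrays there were 116 at day 49, against 188, with 1 mutant array left. A lone array was assumed to vary like the other groups.

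Stricter limits gave fewer calls by construction. With at least 2-fold these were 17, 21, 65 and 21 at day 1, day 20, day 49 and for the mean over ages, 1671 between day 20 and day 1 and 264 between day 49 and day 20. With an adjusted p below 0.01 they were 12, 19, 98 and 173 for the genotype comparisons, 1335 between day 49 and day 20 and 5 for the change with age. With 1 probe set per gene, which tests fewer probe sets, they were 5437, 1950 and 15 for the wild-type comparisons and the change with age, and probe sets above the median level gave 15 for the latter.

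Gene lists depended on how camera treats the correlation between genes. With an estimated correlation 0, 3 and 1 lists were called at day 1, day 20 and day 49, 1 for the mean over ages and 2 and 1 in the wild type, against 4, 6, 9, 9, 13 and 7. At day 1 also fry called 0, against 4 by camera at its preset correlation. Fry called 3 at day 20, 4 at day 49 and 11 between day 49 and day 20. Calls at an unadjusted p below 0.01, a looser limit, overlapped in 73 probe sets between day 1 and day 20, 89 between day 1 and day 49 and 174 between day 20 and day 49, against 10, 9 and 28. The maturation correlation at day 1 changed sign from 0.0172 to -0.000449 among probe sets above the median level, where it was -0.235 at day 49, and Spearman's rho was -0.121 at day 20 and -0.136 at day 49. The cause was not tested.

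Leaving out single arrays gave 15 to 234 calls at day 1, 21 to 32 at day 20, 109 to 161 at day 49, 281 to 524 for the mean over ages, 6811 to 7849 between day 20 and day 1, 1602 to 2591 between day 49 and day 20 and 14 to 58 for the change with age. A group left with 2 arrays was assumed to vary like the other groups. Lists called were 2 to 5, 4 to 11, 7 to 11, 8 to 11, 12 to 14 and 5 to 9 in the order above, and overlaps 5 to 15, 5 to 17 and 17 to 28. Rbm20 stayed between -5.25 and -4.94 at day 1, -5.25 and -4.96 at day 20 and -4.55 and -4.15 at day 49, and Ttn between 0.03 and 0.09, 0.01 and 0.17 and 0.01 and 0.13. The maturation correlation ranged from -0.0515 to 0.0692, from -0.254 to -0.103 and from -0.212 to -0.169 at the 3 ages.

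With the replicate number as a block, the paired reading of the titles, calls numbered 8754 between day 20 and day 1 of the wild type, against 8737. The other comparisons did not meet the limit for a pairing, with correlations above 0.1 in 2 of 3 pairs at day 1 and in 1 of 3 at day 20, at day 49 and between day 49 and day 20. There the block gave 38, 38, 208 and 440 calls for the genotype comparisons, 3054 between day 49 and day 20 and 25 for the change with age, and 4, 7, 9, 9, 13 and 7 lists. Among the single genes and lists named, the block added the calls of Nppa at day 49 (adjusted p = 0.0106) and of the dimmer Myh7 probe set at day 49 (0.0326) and on average (0.0447), and ended 0.

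Further alternatives left the counts of calls and lists within 1.5 times. These were an intensity trend, quantile normalization, centred arrays, Y-linked transcripts and the Gapdh end difference as covariates and the RNA end class as a block. For named genes and called lists 1758 values were computed. Of these, 1557 stayed on their side of the threshold, 182 kept direction and lost the call, and 19 gained one. In 0 cases did the direction turn with a call in either fit. Values past the threshold in neither fit counted as unchanged even where their sign turned. An example was the dimmer Myh6 probe set at day 1, at 0.02 with all arrays and -1.14 without mutant array 3. Of the losses 45 came from leaving out arrays, 40 from camera with an estimated correlation and 23 from fitting only the arrays of the ages compared. Dim probe sets, whose level is mostly background, compress differences, and the number of arrays limits what can be called.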

Other observations

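The test on the neighbours of Rbm20 was chosen only after the result was seen, and the test on probe sets of splice targets was planned but its adjustment over 4 comparisons and the count of dim probe sets were added afterwards.

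Genes close to Rbm20 in the mouse gene order (GRCm38.p6) held more calls on the mean over ages than other genes. Of 60 neighbours within 30 places on either side 5 were called, Pdcd4, Bbip1, Nrap, Tdrd1 and Trub1, chosen after their values were seen, or 8.33% against 2.10% of other genes (two-sided Fisher exact p = 0.00887, 0.0118 adjusted over 4 comparisons). Windows of 10, 20, 60 and 100 places gave an exact p of 0.0667, 0.00151, 0.0622 and 0.127, so the result rested on the window. At single ages the exact p within 30 places was 0.00301, 0.00449 and 0.0146. Bbip1 differed by -1.36, -1.35 and -1.37 at the 3 ages, Trub1 by 0.55, 0.61 and 0.50 and Nrap by 0.36, 0.28 and 0.23. Values were less even for Tdrd1 (0.03, 0.26 and 0.89) and Pdcd4 (0.89, 0.91 and 0.28 in its brightest probe set). A stretch of chromosome inherited along with the mutation from one parent strain may carry variants that change nearby transcripts or the binding of their probes. The mutation itself could also act on its surroundings, and neighbouring genes share regulation, so these cannot be told apart. The rat gene order was not used here. Genes were matched to the mouse order by identical symbol alone, 13108 of them besides Rbm20, so a neighbour under another symbol was not counted. Fhip2a, called at all ages, was not among the 60, and whether its symbol had a match was not checked.

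A loss of RBM20 may change splicing, so that probe sets of one gene move apart between genotypes. On the mean over ages 46 of 6609 pairs of probe sets of a gene, from 40 genes, differed in their genotype effect. Of 24 splice targets with such pairs 2 were among these, Enah and Lrrfip1, or 8.33% against 0.844% of other genes (two-sided Fisher exact p = 0.0186, 0.0744 adjusted over 4 comparisons). At day 49 it was 1 of 24, Enah (exact p = 0.120), and at day 1 and day 20 it was 0 of 24, with 2 and 3 pairs called in all. Differences of dim probe sets are compressed, which could also move pairs apart. In 26 of the 46 pairs the dimmer probe set lay below the median level of 5.47, among them one of Enah (4.06 against 8.71). Another called Enah pair, at 0.39 and 0.99, lay just above that median (5.65 against 8.71). The Lrrfip1 probe sets differed in opposite directions, by -0.28 and 0.34, at levels of 8.05 and 8.95, both above that median. The targets are too few for the test to decide between splicing and compression, and where the probes lie relative to the exons was not used here.

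Ephx2, chosen after its values were seen, had low and high levels within groups. On the log2 scale the mutant arrays were at 5.70, 5.29 and 7.78 at day 1, 5.89, 5.89 and 5.34 at day 20 and 7.94, 8.31 and 7.64 at day 49. The wild-type arrays were at 7.91, 5.59 and 5.64, at 9.08, 9.02 and 8.95 and at 8.24, 7.48 and 7.22. Of the 188 probe sets called at day 49, 55 had no single gene symbol and remain without a name here. Of the 8 called at all ages 4 had none. The largest of these at day 1 and day 20 differed by -2.53, -2.70 and -2.01 at the 3 ages, and another was at 2.12 at day 49.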
